A study of Mus musculus with 2 samples.

How the data were processed

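The series holds 2 single-cell RNA libraries, 1 of sorted splenic CD4+ Foxp3+ cells (Treg) and 1 of sorted CD4+ Foxp3− cells (Tconv), each from 3 pooled male C57BL/6 Foxp3-GFP mice. Per the labels' protocols, libraries were made with the 10x Chromium Single Cell 3' kit, which reads the 3' ends of transcripts with unique molecular identifiers (UMIs), and sequenced on an Illumina instrument with paired ends. The deposited values are raw UMI counts per cell and gene, with no normalization, as whole numbers with totals that differ between cells. The submitters' processing notes name the build GRCm38. The aligner, counter, annotation and any filter on cells or genes before deposit are not given in the sources used here. Each deposited table lists only genes with at least 1 UMI in that library: 13253 genes were in both, 964 only in Treg and 942 only in Tconv. Symbols were matched to a GENCODE mouse annotation on GRCm38, which gave coordinates and spelling, for 97.35% of the genes of each library. Counts from the 3' end do not tell overlapping genes or near-identical copies apart beyond what the counter did.

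Cells with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept, which left out 282 Treg and 58 Tconv cells. Of these, 251 and 52 were over the mitochondrial limit. Scrublet marked 1 Treg cell, which was left out, and 0 Tconv cells. It therefore did not work as a doublet caller here, and doublets were weighed through cells above 2.5 times the median UMIs. The kept cells held 15063259 UMIs in Treg and 24267424 in Tconv. At these sums a count of 0 allows up to 0.199 CPM (UMIs of a gene per 1000000 UMIs of the library) in Treg and 0.124 CPM in Tconv, taking 3 counts for a count of 0.

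UMIs were summed over the kept cells of each library and given as CPM. Sums have exact Poisson intervals, ratios exact conditional binomial (Clopper-Pearson) intervals and shares of cells exact binomial intervals, all at 95% and for counting error only. Intervals of list medians come from simulated Poisson counts, and those of Ighm per cell between clusters from resampled cells. Intervals of shares of genes are exact binomial intervals over genes taken as independent. Cells are not replicates and each group is 1 library, so no test was run. Genes were counted at a size of 2-fold with at least 100 UMIs over both libraries, and list members at 1.5-fold with at least 20 UMIs. List medians were set against 10000 random lists of the same size matched on mean expression, as a description of these libraries. The interval and size steps were tested on simulated Poisson counts for Treg against Tconv with 9205 genes. In these, 95.5% of intervals held the true ratio. The 2-fold size was passed by 100 of 100 genes changed 4-fold, 2 of 100 genes changed 1.5-fold and 0 of 9005 unchanged genes. The intervals assume Poisson counts too. This checks the steps, and not how the intervals hold for genes with UMIs gathered in few cells.

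Before the data were examined, 25 lists were fixed from textbook knowledge: Treg-up, Treg-down, resting, activated or effector, the same without Treg-up genes and without Cd74, TCR and early response, NF-kB and TNF receptor, IL-2 and STAT5 response, interferon response, cytokines, helper lineage regulators, chemokine receptors and homing, T cell identity, proliferation, heat shock, apoptosis and survival, B cell, myeloid and dendritic, CD8 T cell, NK cell, erythroid and platelet, plasma cell, gamma delta or NKT, MHC class II, and dissociation and RNA quality. The genes named were also fixed by rule. They are Foxp3, the 15 highest and 15 lowest ratios among genes with at least 100 UMIs in the library where they are higher, and up to 4 members of each list with the largest absolute log2 ratios among members with at least 100 UMIs. Receptor and immunoglobulin segments and provisional names were left out of the ranking, and a few other genes were named after their values were seen, among them Id3, Pim2, Ccl5, Id2, Nkg7, Cd79a and Lef1. Values of some genes that the rule names are not reported here.

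For comparisons of single cells, each cell was thinned to 1500 UMIs, which left out 11.8% of Treg cells and 0.325% of Tconv cells. Neighbours were found among 4148 cells per library after log-normalization to 10000, with 2000 variable genes without T cell receptor segments, 30 principal components and 30 neighbours. Each library was clustered alone with 15 neighbours and the Leiden method at resolution 0.8. A cluster was to be called after a class when at least 3 of its markers were among the top 10 genes by fold. As first fixed, this rule had no detection minimum, and genes seen in few cells then led most clusters. After the data were seen, names were kept only where the rule gave the same one among genes with a UMI in at least 10%, 25% and 50% of a cluster's cells. Scaling of each gene, first used in exploration, is not in the fixed design and is given as an alternative. So 4 ways of naming and 2 of scaling were compared.

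Alternatives fixed beforehand were other filters on cells, cells with non-T UMIs left out, TMM scaling with edgeR 4.0.16, the mean of each cell's CPM, ribosomal and mitochondrial genes left out of the sum, thinning, other minimums and sizes, and other settings for neighbours, scores and clusters. Added after seeing the data were a median-gene centring, filters on non-T genes, on CD3 and T cell receptor UMIs and on cells with very high UMIs, and the naming and scaling alternatives above. Python 3.11.15 with scanpy 1.11.5, leidenalg 0.10.2 and scipy 1.17.1 was used, and R 4.3.3 for edgeR.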

Results

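Messenger RNA was counted in single CD4+ T cells from the spleens of male C57BL/6 Foxp3-GFP mice, whose green fluorescent reporter marks cells that express the transcription factor Foxp3. Sorted CD4+ Foxp3+ cells (regulatory T cells, Treg) made 1 library, and sorted CD4+ Foxp3− cells (conventional T cells, Tconv) made the other, each from 3 pooled mice aged 8 weeks. The Treg library listed 4987 cells with 15296734 unique molecular identifiers (UMIs), and the Tconv library listed 5589 cells with 24310953 UMIs. After the filter on cells, 4704 Treg cells (median 2867 UMIs and 1094 genes per cell) and 5531 Tconv cells (median 4132 UMIs and 1249 genes per cell) were kept. With 1 library per group there was no replicate check and no test, so the values compare these libraries. Intervals are 95% intervals, exact except for those of list medians, which come from simulated Poisson counts. Limits for a count of 0 take 3 counts. Both cover counting error only, apart from later intervals of shares of genes and from resampled cells.

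The comparison of Treg with Tconv asks how the transcripts of regulatory cells differ from those of other splenic CD4+ T cells. Foxp3, the gene used for the sort and the master regulator of Treg, was at 159 CPM (UMIs of the gene scaled to a common library sum; interval 153 to 166, 2399 UMIs) in Treg and at 0.165 CPM (0.0449 to 0.422, 4 UMIs) in Tconv, a log2 ratio of 9.92 (8.56 to 11.79). On GRCm38 the gene lies on chromosome X from 7573644 to 7595245, on the plus strand. All 30 genes of the Treg-up list were at least 1.5-fold higher in Treg, with a median log2 ratio of 3.92 (3.71 to 4.0). Lrrc32, which carries latent TGF-beta on the Treg surface (chromosome 7, 98489283 to 98502181), had 1100 UMIs in Treg and 0 in Tconv, so that it was at least 591-fold higher against a floor of 3 counts over the Tconv library. Il2ra, the alpha chain of the IL-2 receptor (chromosome 2, 11642807 to 11693193), had a log2 ratio of 6.72 (6.25 to 7.24), the integrin gene Itgae 6.01 (5.28 to 6.86) and the transcription factor gene Ikzf2 5.40 (5.27 to 5.54).

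Of the 15 genes of the Treg-down list, 14 were at least 1.5-fold lower in Treg, and the median log2 ratio was −1.76 (−1.82 to −1.68). Pde3b, a phosphodiesterase gene (chromosome 7, 114415281 to 114539251), was 37.5-fold lower in Treg, with 13 UMIs against 786. Dapl1 (chromosome 2, 59484653 to 59505020) was 15.5-fold lower and Igfbp4, an IGF binding protein gene, 6.88-fold lower. Themis, a gene of T cell receptor signalling, was 4.78-fold lower. Id3 went the other way, with a log2 ratio of 1.0. The median of the Treg-up list lay above the medians of all 10000 random lists of the same size and mean expression, at percentile 100, and that of the Treg-down list below all of them, at percentile 0.

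**Figure D1:**
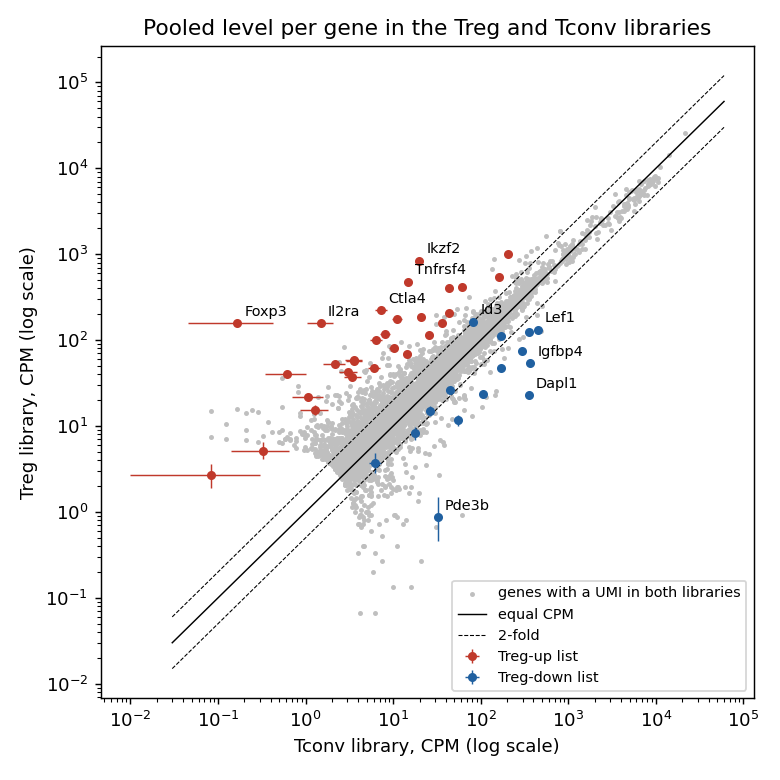
CPM of each gene in the Tconv library (x axis) and the Treg library (y axis), both on log scales, for genes with at least 100 UMIs over both libraries and a UMI in each, and for members of the Treg-up (red) and Treg-down (blue) lists with a UMI in each, with exact Poisson 95% intervals as bars. Foxp3 sits at 159 CPM in Treg and 0.165 CPM in Tconv. Lrrc32, with 0 UMIs in Tconv, is not drawn.

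The 15 genes with the highest ratios included Foxp3, Lrrc32, Il2ra, Itgae and Ikzf2. Besides these, Gbp2b, a guanylate-binding protein gene, had a log2 ratio of 7.50 (5.63 to 10.56), Il10, which encodes an immunosuppressive cytokine, 6.40 (4.82 to 8.69), Sdc4, a heparan sulfate proteoglycan gene, 6.08 (5.29 to 7.0), and Itgb8, an integrin gene, 5.94 (4.80 to 7.40). Atp6v0d2, Matn2, Rln3, Lamc1, Bicd1 and Gsta4 had log2 ratios from 5.16 to 6.56. Among the 15 genes with the lowest ratios were Ggt5 at −6.30 (−8.18 to −4.94), Lypd6b at −6.22 (−9.27 to −4.35), Pdlim4 at −6.03 (−6.90 to −5.28), Pde3b at −5.23 (−6.15 to −4.45) and the chemokine gene Xcl1 at −4.78 (−6.24 to −3.64). Atp8b4, Cd209a, Auts2, App, H2-M2, Dapl1 and Vipr1 had log2 ratios from −6.56 to −3.85, of which Cd209a and H2-M2 were not lower in Treg without cells with 10 or more UMIs of 10 non-T genes. Jchain, Igha and Ccl1 were also among the 15 lowest, but most of their Tconv UMIs (380 of 388, 727 of 750 and 171 of 181) were in 1 cell each. Xcl1 was 425-fold higher in a Tconv cluster of 118 cells (2.13%) than in the other Tconv cells.

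Among 9199 genes with at least 100 UMIs over both libraries, 732 were at least 2-fold higher in Treg and 205 at least 2-fold lower, so that 78.1% of these genes were higher. With TMM scaling of the library sums in place of CPM, 509 were higher and 294 lower, or 63.4% higher. The median log2 ratio of all genes was 0.23 under CPM and −0.03 under TMM. Ribosomal protein genes gave 35.9% of the UMIs in Treg and 44.4% in Tconv. Their median log2 ratio was −0.31 over 82 genes, and 69 of them were below 0. Between both libraries, 77.2% of the genes lay within 1.5-fold of each other.

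Genes of resting (naive or central) T cells were lower in Treg. Of 16 genes, 11 were at least 1.5-fold lower and 0 higher, with a median log2 ratio of −0.80, or −1.03 relative to the median of all genes, at percentile 0. Tcf7, a transcription factor gene of naive and memory T cells, was at −1.98 (−2.07 to −1.89) and Rflnb at −2.65 (−2.85 to −2.47). The list shares 7 genes with the Treg-down list. Over the other 9 genes, a split chosen after the values were seen, 4 were lower and the median was −0.43.

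Genes of activated or effector T cells were higher in Treg. Of 30 genes, 26 were at least 1.5-fold higher and 4 lower, with a median log2 ratio of 1.68, or 1.45 relative to the median of all genes, at percentile 100. Klrg1, a receptor gene of differentiated effector cells, was at 4.63 (4.23 to 5.07), the granule protease gene Gzmb at 4.05 (3.73 to 4.39) and Ccr2, a chemokine receptor gene, at 2.84 (2.62 to 3.06). Ccl5, Id2, Nkg7 and Cd74 were lower. In the list without Treg-up genes and without Cd74, 20 of 23 were higher, and the median was 1.45, at percentile 100. Cd74, the invariant chain of MHC class II, was lower in the sums at −1.13, yet 18.4% of Treg cells and 4.68% of Tconv cells had a UMI of it. Without cells under 3 UMIs of the CD3 and T cell receptor constant genes, Cd74 was higher in Treg, at 0.88, and without cells with 10 or more UMIs of 10 non-T genes it was at 3.32.

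Lists of signalling genes had positive medians. In the NF-kB and TNF receptor list, 14 of 15 genes were higher, 0 lower, and the median log2 ratio was 1.16, or 0.92 relative to the median of all genes, at percentile 100. Its leading members were the TNF receptor family genes Tnfrsf4 at 5.02 (4.87 to 5.18), Tnfrsf9 at 3.98 (3.80 to 4.17) and Tnfrsf1b at 3.21 (2.98 to 3.44), and 3 of its genes are also in the Treg-up list. In the IL-2 and STAT5 response list, 10 of 15 were higher and 1 was lower, Pim2 at −0.80, a gene chosen after its value was seen. The median was 1.0, or 0.77 relative to the median of all genes, at percentile 100, with Il2rb at 3.16 and Cish, a feedback inhibitor gene of cytokine signalling, at 3.06, and 4 of its genes are in the Treg-up list. In the TCR and early response list, 14 of 25 measured genes were higher and 1 lower, with a median of 0.67, or 0.43 relative to the median of all genes, at percentile 100. Nr4a2 was at 1.70 (1.26 to 2.15), Dusp5 at 1.52 (1.31 to 1.74) and Tnfaip3, which encodes an inhibitor of NF-kB, at 1.48 (1.28 to 1.68). In the interferon response list, 7 of 20 were higher and 2 lower, and the median was 0.52, or 0.29 relative to the median of all genes, at percentile 99.96. Gbp2 was at 1.39 and Ifi27l2a at 1.23, and Oasl2 at −1.13. Oasl2 was at −1.14 without cells with 10 or more UMIs of 10 non-T genes. It was at −1.06 without cells under 3 UMIs of the CD3 and T cell receptor constant genes. Without cells with 2 or more UMIs of the non-T lists it was at 0.16. That filter uses the myeloid and dendritic list, which shares 1 gene, Bst2, with the interferon response list, so it also selects on an interferon response gene.

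Of 11 measured cytokine genes, 5 were higher and 3 lower, with a median log2 ratio of 0.53, or 0.30 relative to the median of all genes, at percentile 95.5. Besides Il10, Ebi3, a subunit of the cytokine IL-35, was at 3.33 (2.75 to 3.96) and Lta at 1.52 (1.29 to 1.76), while Ifng was at −0.75 (−1.08 to −0.43). Of 14 helper lineage regulators, 6 were higher and 2 lower, with a median of 0.34, or 0.11 relative to the median of all genes, at percentile 81.8. Irf4 was at 2.71 (2.22 to 3.23) and Maf at 2.07 (1.98 to 2.17), and Eomes was at −2.41 (−3.36 to −1.57). Of 21 chemokine receptor and homing genes, 13 were higher and 4 lower, with a median of 0.84, or 0.60 relative to the median of all genes, at percentile 100. Ccr8 was at 3.70 (2.83 to 4.70) and Ccr6 at 3.19 (2.74 to 3.66).

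In the proliferation list, 14 of 20 genes were higher in Treg and 0 lower, with a median log2 ratio of 1.23, or 1.0 relative to the median of all genes, at percentile 100. Ccna2 was at 2.01 (1.67 to 2.35) and Mki67, a marker gene of cycling cells, at 1.97 (1.72 to 2.23). Without cells above 2.5 times their library's median UMIs, the median was 0.62, with 10 genes higher and 1 lower, and with every cell thinned to 1500 UMIs it was 0.72. The filter on high UMIs also takes out many cells of a Treg cluster led by the cell division genes Esco2 and Cep55 (89 cells, median 9523 UMIs). Tconv also held a cluster led by Nusap1 and Neil3 (38 cells, median 10046 UMIs). Both genes were among the leading genes of that Treg cluster too. Without cells with 2 or more UMIs of the non-T lists, a filter that leaves out 71.2% of Treg and 60% of Tconv cells, 8 were higher and 1 lower and the median was 0.36. Treg cells left out by it had a median of 3071.5 UMIs, against 2402.5 in the others, so it also takes out deeper cells. Of 15 apoptosis and survival genes, 8 were higher and 1 lower, with a median of 0.82, or 0.58 relative to the median of all genes, at percentile 100. Bcl2l1, which encodes the survival protein Bcl-xL, was at 2.13 (1.85 to 2.42) and the Fas ligand gene Fasl at −1.25 (−1.81 to −0.73). Of 16 T cell identity genes, 2 were higher, 2 lower and 12 between, with a median of 0.12 that turned to −0.14 under TMM scaling, at percentile 30. Cd2 was at 1.12. Of 10 heat shock genes, 0 were higher and 2 lower, with a median of −0.06, or −0.30 relative to the median of all genes, at percentile 1.32, and Hspa1a was at −1.43 (−1.62 to −1.25). All 9 genes of the dissociation and RNA quality list lay within 1.5-fold, with a median of −0.12, or −0.36 relative to the median of all genes, at percentile 2.38.

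**Figure D2:**
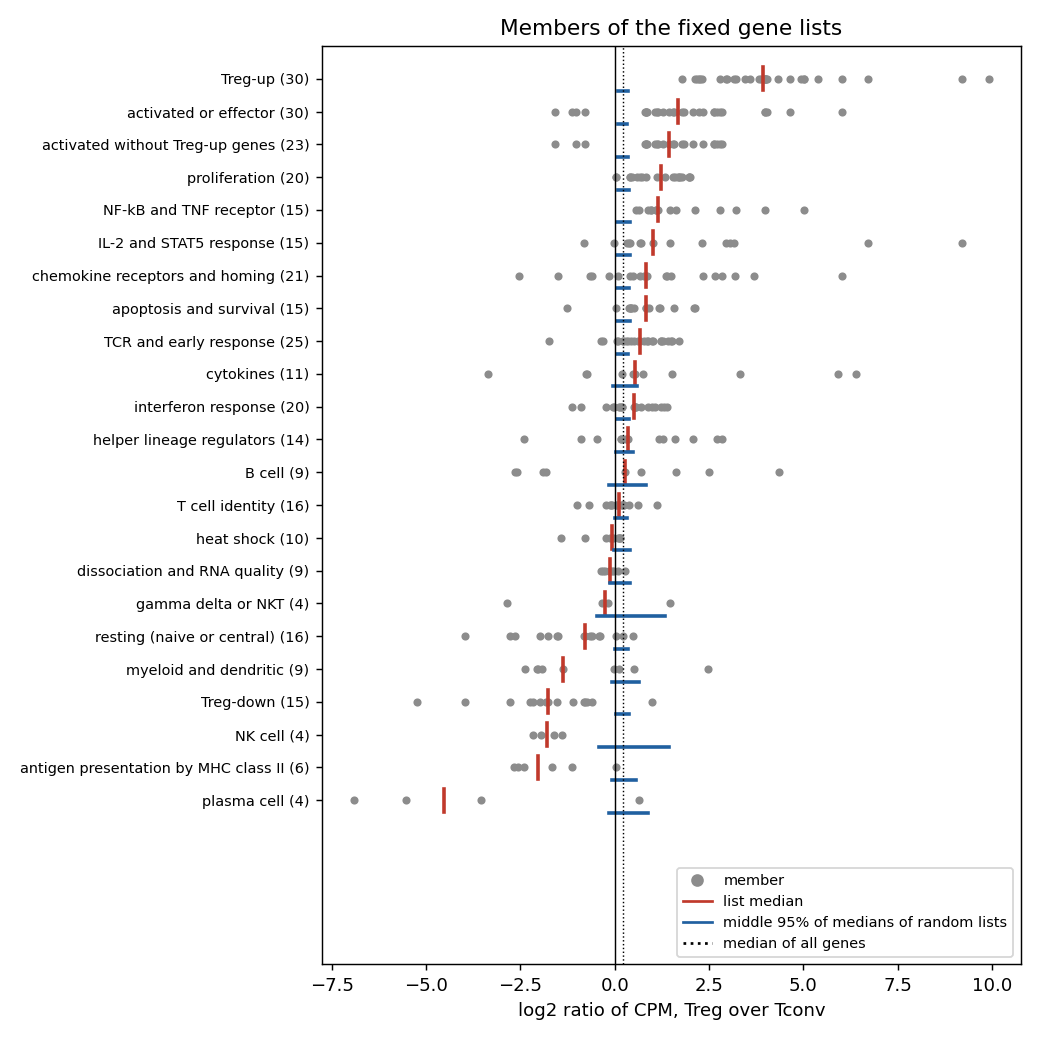
log2 ratio of CPM, Treg over Tconv (x axis), for each measured member (grey points) of the gene lists with at least 4 measured members, whose number stands in brackets. Red bars are list medians, blue lines the middle 95% of the medians of 10000 random lists matched on expression, and the dotted line the median of all genes at 0.23. Lrrc32 is drawn at its lower bound. The Treg-up median is 3.92 and the Treg-down median −1.76. The T cell identity median of 0.12 turns to −0.14 under TMM scaling.

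Markers of other cell types were measured in both sorts. In the MHC class II list, 0 of 6 genes were higher in Treg and 5 were lower, with a median log2 ratio of −2.03 at percentile 0, and H2-Aa was at −2.56 (−2.72 to −2.41). Without cells under 3 UMIs of the CD3 and T cell receptor constant genes the median was −0.70, and without cells with 10 or more UMIs of 10 non-T genes it was −0.23. In the myeloid and dendritic list, 1 of 9 measured genes was higher (Lyz2, 2.48) and 5 were lower, with a median of −1.36 at percentile 0 that turned to 0.13 and 0.26 under the same filters. In the plasma cell list, 1 of 4 measured genes was higher (Xbp1, 0.64) and 3 were lower, with a median of −4.54 at percentile 0. The plasma cell median was −0.22 without cells with 10 or more UMIs of 10 non-T genes. It was −4.36 without cells under 3 UMIs of the CD3 and T cell receptor constant genes. In the NK cell list, all 4 measured genes were lower, with a median of −1.78 at percentile 0.05, Klrb1c being at −2.18 (−3.10 to −1.36). Klrb1c was 652-fold higher in a Tconv cluster of 118 cells (2.13%) than in the other Tconv cells. In the B cell list, 4 of 9 measured genes were higher and 4 lower, with a median of 0.26 at percentile 49.5, and 1.58 with every cell thinned. Without cells with 10 or more UMIs of 10 non-T genes, which are 11 Treg and 57 Tconv cells, all 9 were higher and the median was 1.64. Without cells under 3 UMIs of the CD3 and T cell receptor constant genes, 4 were higher and 3 lower, and the median was 0.25. Ighm, the constant region of immunoglobulin M, was 3.06-fold higher in Treg, at 848 CPM (833 to 863) against 277 CPM (270 to 283). Igkc was at −2.60, with 1724 of 1917 Tconv UMIs in 1 cell, and at 0.55 without the top cell of each library. In the gamma delta or NKT list, 1 of 4 measured genes was higher and 1 lower, with a median of −0.25 at percentile 6.24. In the CD8 T cell list, 1 of 2 genes was higher and the median was 1.02 at percentile 83.0. The erythroid and platelet list had 0 measured genes. Without cells with 2 or more UMIs of the non-T lists, a filter that selects on the NK, myeloid and dendritic, plasma and B cell genes themselves, Ighm among them, these medians were 1.41, 1.41, 1.2 and 0.93, with 3 NK cell genes higher and 0 lower. Under it the lists it does not select on were at 0.57 (gamma delta or NKT), −0.41 (CD8) and −0.59 (MHC class II).

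In single cells, 34.2% of Treg cells (1611 of 4704, 32.9% to 35.6%) and 0.0723% of Tconv cells (4 of 5531, 0.0197% to 0.185%) had a Foxp3 UMI. After every cell was thinned to 1500 UMIs, which left out 556 Treg cells and 18 Tconv cells, the shares were 21.1% (19.9% to 22.4%) and 0.0363% (0.0044% to 0.131%). Ikzf2 had a UMI in 57.1% of thinned Treg cells and 2.39% of thinned Tconv cells, and Tnfrsf4 in 36.4% and 1.65%. Lrrc32 had a UMI in 10.4% of thinned Treg cells and in 0 of 5513 thinned Tconv cells, which allows a share of cells with a UMI of up to 0.0544% at 3 counts. Dapl1 had a UMI in 1.88% of thinned Treg cells and 27.3% of thinned Tconv cells, and Lef1 in 17.6% and 46.2%. As a background, the B cell gene Cd79a had a UMI in 0.289% of thinned Treg cells and 0.127% of thinned Tconv cells, and in 0.659% and 0.235% before thinning, at median depths of 2867 and 4132 UMIs. Other such genes were seen in more cells before thinning, Cd79b in 5.31% of Treg cells and 0.886% of Tconv cells.

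A score per thinned cell, the mean log-normalized level of Treg-up genes minus that of Treg-down genes, had a median of 0.27 in Treg and −0.34 in Tconv. A Treg cell scored above a Tconv cell with probability 0.953, the area under the curve. Among 4148 thinned cells drawn from each library, the median cell had 3.33% of its 30 nearest neighbours in the other library, against 50% with shuffled library labels. Most neighbours came from the other library for 306 Treg cells (7.38%, 6.60% to 8.22%) and 106 Tconv cells (2.56%, 2.10% to 3.08%). Each group is 1 library, so a difference between libraries of another kind is part of these values.

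**Figure D3:**
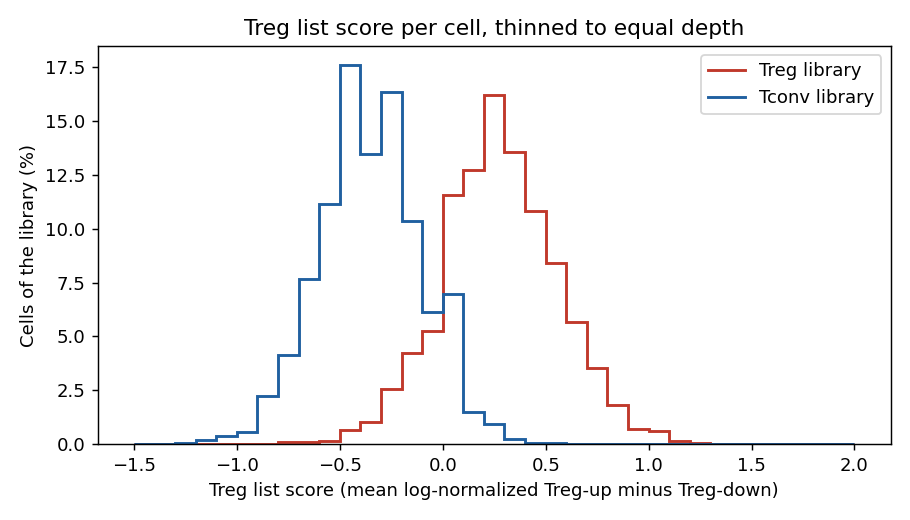
Share of cells (y axis, percent of the library) by Treg list score (x axis, mean log-normalized level of Treg-up genes minus that of Treg-down genes) after thinning to 1500 UMIs, for 4148 Treg cells (red) and 5513 Tconv cells (blue). The median score is 0.27 in Treg and −0.34 in Tconv.

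Clustered alone, each library gave 10 clusters, and 2 in each met the marker rule at all 3 detection minimums. In Treg, 533 cells (11.3%, 10.4% to 12.3%) formed an activated-like cluster, named by S100a4, S100a6, Ccr2, S100a11 and Lgals1, and 11 cells (0.234%) a myeloid or dendritic-like cluster with 0 Foxp3 UMIs. In Tconv, 802 cells (14.5%, 13.6% to 15.5%) formed an activated-like cluster, named by Maf, Ahnak, Cxcr3, S100a6, Itgb1, Cd44 and S100a11, and 278 cells (5.03%, 4.47% to 5.64%) an interferon-like cluster, led by Ifit3, Ifit1 and Isg15. The rule named no myeloid or dendritic-like cluster in Tconv. Unnamed Tconv clusters of 40 cells and 13 cells held the MHC class II gene H2-Aa at 12122 and 3168 CPM. In the 11 Treg cells it was at 6683 CPM. The names depend on the detection minimum: with names from all genes, 0% of cells in either library were activated-like, and the Tconv cluster of 802 cells was plasma cell-like. Unnamed Treg clusters of 920 cells (19.6%) and 797 cells (16.9%) met the resting rule at a minimum of 25%. The libraries differ in the genes that define clusters, so cluster sizes were not compared between them.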

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

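The tests of explanations in this part were chosen after the results were seen, although leaving ribosomal and mitochondrial genes out of the sum and thinning had been fixed beforehand as alternatives. Cells that failed the filter entered only the alternative without a filter, and 9.93% of the 282 Treg cells among them (28 cells, 6.70% to 14.0%) had a Foxp3 UMI, against 0 of 58 Tconv cells, which allows up to 5.17% at 3 counts, or 6.16% as an exact upper limit. Their median was 662 UMIs and 12.7% mitochondrial UMIs in Treg.

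More genes were at least 2-fold higher than lower in Treg, 78.1% of those apart. Without ribosomal protein and mitochondrial genes in the sum the share was 67.0% (63.6% to 70.2%). This interval and the next take genes as independent draws and do not cover a difference between libraries. More genes were still higher than lower, which argues against the lower ribosomal share in the sum as the whole cause. Part of the excess goes with it. With every cell thinned to 1500 UMIs the share was 82.8% (79.4% to 85.8%). Thinning leaves the expected share of each gene in a cell's UMIs unchanged, so this value cannot decide whether depth per cell has a part. A difference between the sorted populations may remain, and it was not tested, because each group is 1 library and any other difference between libraries is confounded with it.

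A Foxp3 UMI was seen in 34.2% of Treg cells although all were sorted on the Foxp3 reporter. Counting alone, from the pooled level and each cell's depth, gives 37.6%, so that few UMIs per cell could account for most cells without one. The pooled level comes from the same cells, so this value cannot exclude that a part of them held no Foxp3 RNA. Tconv cells in the sort are argued against as the whole cause, since thinned Treg cells without a Foxp3 UMI held a mean of 8.46 UMIs of the other Treg-up genes, against 9.69 in those with one and 1.09 in Tconv cells. A small share of Tconv cells stays open.

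Ighm was 3.06-fold higher in Treg and had a UMI in 75.3% of Treg and 60.6% of Tconv cells, in a sort on CD4 that would remove B cells. Without cells under 3 UMIs of the CD3 and T cell receptor constant genes, which are 62 Treg and 52 Tconv cells, its log2 ratio was 1.63. This argues against B cells that lack T cell receptor UMIs as the whole cause. Droplets that hold both a T cell and a B cell can pass this filter, and Igkc stayed at −2.75 under it. So it cannot decide whether such droplets have a part. Free RNA that enters all droplets alike would give each cell about as much, but between the highest and lowest Treg clusters of like depth, made without B cell genes and picked on other cells than those measured, Ighm was at 5.27 and 1.36 UMIs per cell, a log2 ratio of 1.95 (1.75 to 2.14 from resampled cells), or 1.59 (1.41 to 1.77) as CPM, which argues against it as the whole cause. In Tconv the ratio per cell was 0.44 (−0.07 to 0.89), so free RNA stays open there and for a part of the Treg level. RNA of B cells held by some of the cells, and transcription in T cells, also stay open and were not tested, since clusters 0 and 4 over clusters 1, 2 and 3, where Ighm differed by 1.57, Igkc by 4.25 (3.22 to 5.50), Cd74 by 2.71 (2.52 to 2.91) and Cd79b by 1.52 (1.13 to 1.93), were picked for their Ighm levels. Of the 103 Igkc UMIs in clusters 0 and 4, 37 were in 5 cells. Counted by cells with a UMI, Igkc differed by 3.04 (1.87 to 4.45).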

How the results depend on the processing

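Of 149 alternative values for 15 results, 94 stayed within the counting interval or 1.5 times the count, 55 moved and 0 changed sign. Only the Foxp3 ratio and the Treg-up, Treg-down, resting and activated medians can change sign, as the other results are counts, shares or an area. Medians of other lists are not among the 15 results, and some of them, such as T cell identity, did change sign. The alternatives added after seeing the data were 47. The cause of a move was not tested unless named. No paired analysis was possible because each group is 1 library and no result comes from a test. Depth limits genes with few UMIs in Tconv, such as Foxp3 with 4.

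Higher and lower genes (732 and 205) were 284 and 81 without cells with 2 or more non-T UMIs, a filter that leaves out 71.2% of Treg and 60% of Tconv cells, and 471 and 98 thinned, both with fewer UMIs. They were 1323 and 458 at 20 UMIs, 318 and 68 at 500, 2893 and 744 with no minimum, and 1713 and 384 at 1.5-fold.

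The medians of the Treg-up, Treg-down, resting and activated lists were 3.66, −2.02, −1.06 and 1.42 with TMM, 3.70, −1.97, −1.02 and 1.46 without ribosomal and mitochondrial genes in the sum, and 3.69, −1.99, −1.03 and 1.45 centred on the median gene, each a shift of all genes. Without cells with 2 or more non-T UMIs the last 3 were −1.55, −0.59 and 1.40. Ighm is a gene of this filter. It was at 1392 CPM in the activated-like Treg cluster, and at 488 and 437 CPM in the Treg clusters of 920 and 797 cells. Whether the filter thereby takes out more activated Treg cells was not tested. The Treg-up median was 4.01 without cells above 2.5 times the median UMIs. The activated median was 1.95 without cells with 10 or more UMIs of 10 non-T genes, 1.80 with the CD3 and T cell receptor filter and 1.55 thinned.

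The Treg share with a Foxp3 UMI was 32.9% with no filter, 35.8% at 1000 UMIs and 5% mitochondrial, 25.7% without cells with 2 or more non-T UMIs and 21.1% thinned. The Tconv share was 0% without cells with non-T UMIs. The area under the curve was 0.963 for Treg-up genes alone and 0.975 without thinning. The median share of neighbours was 0% with 15 neighbours, without thinning or with scaled genes, and 10.0% without Treg-up and Treg-down genes.

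Clusters numbered 4 in Treg and 6 in Tconv at resolution 0.4. Activated-like cells in Treg were 0% with names from all genes or at resolution 0.4, 6.48% at resolution 1.2, 14.1% with 20 components, 16.9% with 1000 variable genes, 14.9% with scaled genes and 15.3% with names at the 50% minimum. In Tconv they were 0% with names from all genes or 1000 variable genes, 15.7% at resolution 0.4 and 13.2% at 1.2.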

Other observations

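These values come from clusters of 1 library each, which were looked at after the data were seen. In Treg, an unnamed cluster of 979 cells (20.8%) was led by Ccl5, Cd83, Nrn1 and Tnfrsf9, and held the TNF receptor gene Tnfrsf4 at 1077 CPM and Foxp3 at 222 CPM (205 to 240). Foxp3 was at 144 CPM (131 to 159) in a cluster of 920 cells led by Bcl2, Gpr83 and Il2ra, and at 126 CPM (113 to 141) in a cluster of 797 cells led by Ly6c1, Satb1 and S1pr1. A cluster of 131 cells was led by Irf8, Hivep3 and Srm, and one of 89 cells by the cell division genes Esco2 and Cep55, at a median of 9523 UMIs.

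Another Treg cluster of 188 cells had a median of 844 UMIs, 4.85% ribosomal protein UMIs and 7.33% mitochondrial UMIs, against medians of 35.5% and 2.39% over all Treg cells. Fgl2, Ccr2 and Cxcr3 led it, and Foxp3 was at 231 CPM (170 to 307). A Foxp3 UMI was seen in 20.2% of its cells, against 34.2% of all Treg cells. The sum behind CPM holds ribosomal protein UMIs, so their low share here raises the CPM of other genes. In Tconv, 118 cells (2.13%) formed an unnamed cluster led by Klrb1c, Xcl1 and Cxcr6, with Il4 also among its leading genes. Another 328 cells (5.93%) were led by Myb and Itm2a, and 40 cells (0.723%) by H2-M2, Plbd1 and Il1b.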
